A study of Homo sapiens with 6 samples.

How the data were processed

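RNA enriched for mRNA had been sequenced from ACHN cells as 6 paired-end Illumina libraries, per the labels' protocols, with 3 libraries from cells with a control hairpin and 3 from cells with a hairpin against DNAJC2. The deposited table held raw counts of reads per gene, with an Ensembl identifier and a gene name for each row and 1 column per library, and the authors had applied no normalization to it. That the values were unnormalized counts was read from the values, which were whole numbers with a different total in each library. The genome build was GRCh38 (hg38), per the submitters' processing notes. The aligner, the counting program, the gene annotation release and the strand setting were not given in the sources used here. Reads from antisense or overlapping neighbours, and from pseudogenes or near-identical copies, therefore could not be told apart from a gene's own, and values of such genes (ferritin and ribosomal protein genes among them) are uncertain.

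Columns were matched to libraries by their names, which were the library titles. Of the 20532 genes in the table, 20279 were matched by identifier to GENCODE 29, of which 19735 were protein coding, and 647 genes were named only by their identifier. Coordinates were taken from that annotation on GRCh38. Length and GC content are those of the longest annotated transcript of each gene, which need not be the one expressed. Total counts ranged from 17491462 to 25760291, and 15900 to 16336 genes had at least 1 count. A gene with 0 counts could have had up to 3 counts, which is 0.116 to 0.172 CPM depending on the library. Such floors cover counting error only, since reads without molecular identifiers are not independent molecules.

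The 2 groups were compared with edgeR 4.0.16 in R 4.3.3, with its quasi-likelihood F test (two-sided), TMM normalization, the filterByExpr filter on low counts and Benjamini-Hochberg adjustment, with a threshold of 0.05. Group was the only term in the model. CPM values are TMM-normalized, and log2 CPM used a prior count of 2. Confidence intervals of log2 fold changes are at 95%. A count of genes changed at least 2-fold added a fitted log2 fold change of 1 or more in size. Gene lists with at least 5 tested members were tested with camera from limma 3.58.1 with a preset correlation between genes of 0.01, adjusted over the lists. The 35 lists, the panel of 11 genes, the tests and the other settings to be tried were all fixed before the data were examined. The lists covered ferroptosis, iron, stress responses, metabolism, growth, inflammation, kidney identity and markers of other cell types.

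The text names DNAJC2 and the 11 panel genes whatever their result. It also names the 8 largest rises and 8 largest falls by log2 fold change among genes with an adjusted p under 0.05, a mean of at least 5 CPM, a symbol and no overlap between groups. From each list described it names up to 3 passing members with the smallest p, or up to 2 members as values only where none passed. Since no gene passed over all 6 libraries, the same rule was also applied to the fit without shCtrl 3. That step was added after the data had been seen. Any gene outside this rule is said to have been chosen after its values were seen.

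The other settings fixed in advance were other size factors, 2 other low-count filters, DESeq2 1.42.0, limma-voom, an adjusted p under 0.01, edgeR's test against a 2-fold change, a block for replicate number, an estimated correlation or the rotation test fry for lists, and leaving out each library in turn. Settings added later were the residual first principal component, the mean of the ATF4 list in each library and a GC correction, used as covariates or offsets. The scripts were tested on simulated counts with the real means and library sizes. Each gene was drawn independently of the others, and changes were planted only in genes above a count floor. Over all 6 libraries (13988 genes), edgeR recovered 5.97% of genes changed 1.5-fold, 44.8% of those changed 2-fold and 98.5% of those changed 4-fold, with 4 false calls. Simulated on the 14201 genes without shCtrl 3, the shares were 55.2%, 95.5% and 100%, with 14 false calls. A shift of 1.5-fold simulated in the glycolysis list was called, with 1 of the other 33 lists. In the real libraries genes moved together, with an estimated correlation of 0.523 in the glycolysis list and 0.980 in the ATF4 list. The simulations therefore check the scripts and give neither the power nor the error rate of the tests in these data.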

Results

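RNA abundance per gene was measured in cells that the labels name ACHN, a human renal carcinoma line, and assign to clear cell renal cell carcinoma. Lentiviral short hairpin RNA had been used to lower DNAJC2 in 3 libraries (shDNAJC2 1, 2 and 3), and 3 libraries carried a control hairpin (shCtrl 1, 2 and 3). DNAJC2 encodes a co-chaperone that pairs with HSPA14 in the ribosome-associated complex, which handles nascent chains as they leave the ribosome. The deposited table gave raw counts for 20532 genes. Total counts were 22687843, 24895111 and 25760291 in shCtrl 1, 2 and 3, and 19904686, 17491462 and 24308609 in shDNAJC2 1, 2 and 3. The libraries were described as biological replicates, and nothing stated whether they came from separate transductions, so p-values measured the spread between these libraries. The stated interest of the series was in metabolism and in ferroptosis, the iron-dependent cell death driven by lipid peroxides.

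DNAJC2 mRNA was lower in each knockdown library than in each control library. The mean level of ATF4 target, NRF2 target, hypoxia and glycolysis genes was higher, and that of interferon-stimulated, mitotic, cholesterol synthesis and mesenchymal genes lower, in each knockdown library than in shCtrl 1 and shCtrl 2. Over all 6 libraries these list shifts passed camera with a preset correlation between genes, and none passed with an estimated correlation (smallest adjusted p = 0.517). The control library shCtrl 3 had a control level of DNAJC2 and, for most of these genes, a level close to that of shDNAJC2 1 and shDNAJC2 2. More than 2-fold differences numbered 2080 genes between shCtrl 1 and shCtrl 3 and 2084 genes between shCtrl 1 and shDNAJC2 1.

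DNAJC2 (ENSG00000105821, protein coding, chromosome 7, 103312474 to 103344873 on GRCh38) was at 76.7, 69.8 and 86.5 CPM (TMM-normalized) in shCtrl 1, 2 and 3. It was at 51.2, 50.4 and 38.5 CPM in shDNAJC2 1, 2 and 3. The group means were 77.7 ± 8.40 and 46.7 ± 7.12 CPM (SD, n = 3 each). The fitted knockdown level was 60.1% of control (95% confidence interval 47.0 to 76.8%), a log2 fold change of −0.74 with a standard error of 0.15. Its adjusted p was 0.43 in edgeR's quasi-likelihood test, where it ranked 9 by p among 13988 genes. It was 0.04997 by DESeq2 and 0.0080 in edgeR without shCtrl 3. A two-sided exact permutation test gave p = 0.1, the smallest that 3 libraries against 3 allow. The partner gene HSPA14 was at 25.5, 26.9 and 28.2 CPM in the controls and at 36.4, 33.2 and 33.3 CPM in the knockdown libraries, a log2 fold change of 0.35 with a 95% interval of 0.10 to 0.60. It did not pass after adjustment over all genes.

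Of the 13988 genes tested, edgeR called 0 higher and 0 lower in the knockdown (smallest adjusted p 0.43), with 1585 genes at an unadjusted p under 0.05, of which 559 were higher and 1026 lower. About 699.4 such genes would be expected by chance. limma-voom called 0 genes, with 1473 at an unadjusted p under 0.05, and DESeq2 called 18, with 4 higher and 14 lower. The groups did not overlap for 2204 genes (15.8%, against 10% by chance). Both values by chance are averages. Genes moved together, so counts can lie far from these averages by chance, and neither excess was tested. Of 14201 genes tested without shCtrl 3, edgeR called 2532 higher and 2413 lower, and 630 and 748 of these differed at least 2-fold. That library was singled out after the data had been seen, so the counts without it describe 2 control libraries against 3 and are not an independent test. Counts of list members that rose or fell in that fit are to be read against these shares of all genes.

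The first principal component held 79.4% of the variance and did not separate the groups. It placed shCtrl 1 and shCtrl 2 at 52.6 and 51.0, shDNAJC2 1 and 2 at −34.3 and −34.6, shCtrl 3 at −36.1 and shDNAJC2 3 between them at 1.40. Genes that differed more than 2-fold numbered 48 between shCtrl 1 and shCtrl 2, and 78 between shCtrl 3 and shDNAJC2 2. Of 4855 genes that were called without shCtrl 3 and also tested with it, shCtrl 3 lay nearer to the knockdown mean for 4481 (92.3%).

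**Figure D1:**
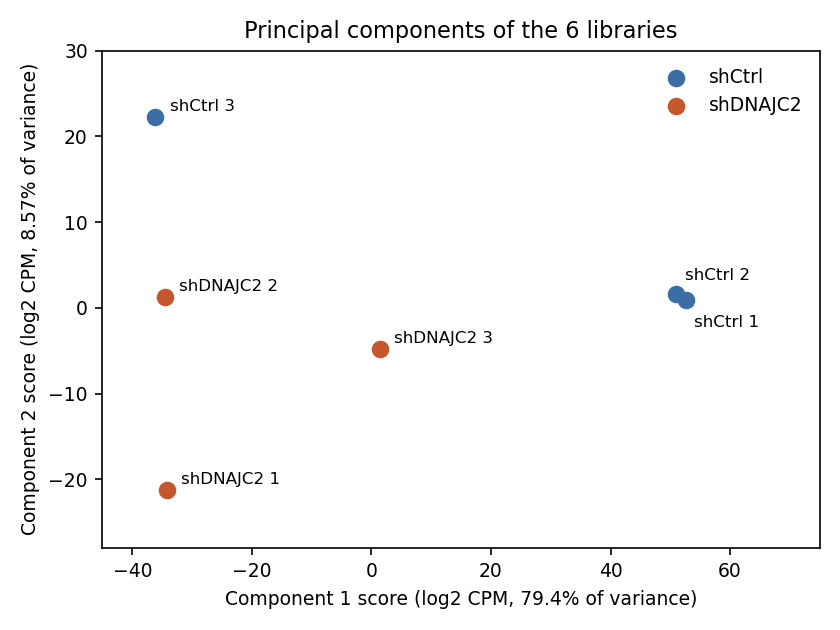
Scores of the 6 libraries on the first (79.4% of variance) and second (8.57%) principal components of log2 CPM, with control libraries in blue and knockdown libraries in orange. The first axis places shCtrl 3 at −36.1, beside shDNAJC2 1 and 2, and far from shCtrl 1 and shCtrl 2 at 52.6 and 51.0.

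Of the named genes from the ferroptosis panel and lists, some separated the groups, some were high in shCtrl 3 as in the knockdown libraries, and others differed little. ACSL4, which loads polyunsaturated fatty acids into membrane lipids and so favours ferroptosis, was at 109, 115 and 127 CPM in the controls and 171, 145 and 152 CPM in the knockdown libraries, a log2 fold change of 0.42 (95% interval 0.15 to 0.68). PTGS2, a common expression marker of ferroptosis, was at 33.0, 36.3 and 94.5 CPM in the controls and at 144, 123 and 185 CPM in the knockdown libraries, with a log2 fold change of 1.46 and a standard error of 0.42, and without shCtrl 3 it rose by 2.12. PTGS2 was not in the panel and was named for its small p among 30 tested genes that favour ferroptosis. Its separation of the groups was therefore selected for. GPX4, the peroxidase that detoxifies lipid peroxides, showed no detectable difference, at 153 ± 11.3 CPM in the controls and 144 ± 9.06 CPM in the knockdown (SD, n = 3), with a log2 fold change of −0.08 (95% interval −0.34 to 0.17) whose sign turned once the GC trend of each library was removed. None of these passed over all 6 libraries after adjustment over all genes. Of the 11 panel genes 0 passed in edgeR, 2 had an unadjusted p under 0.05 (ACSL4 and HSPA14), and 0 passed when adjusted over the list alone, where the smallest adjusted p was 0.0664. DESeq2 called 0 of the 11.

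SLC7A11, the cystine importer that supplies glutathione synthesis, was at 84.2 and 75.3 CPM in shCtrl 1 and 2 but at 673 CPM in shCtrl 3, against 826, 740 and 618 CPM in the knockdown libraries. FTH1, the heavy chain of the iron store ferritin, was at 1394, 1570 and 6790 CPM in shCtrl 1, 2 and 3 and at 5783, 6232 and 4365 CPM in shDNAJC2 1, 2 and 3. HMOX1, which degrades haem and releases iron, was at 15.4, 18.6 and 1198 CPM in the controls and 752, 886 and 145 CPM in the knockdown libraries. Their log2 fold changes over all libraries were 1.39 (95% interval −0.59 to 3.38), 0.75 (−0.71 to 2.21) and 0.53 (−3.21 to 4.28). Without shCtrl 3 all 3 rose, by 3.19, 1.89 and 5.13, and so did AIFM2, TFRC (0.60), ACSL4 (0.48) and HSPA14 (0.39), which made 7 of the 11 panel genes. GPX4, NCOA4, LPCAT3 and NFE2L2 did not pass in either fit. FTH1 has many processed pseudogenes, and how the authors' counting divided such reads was not stated.

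**Figure D2:**
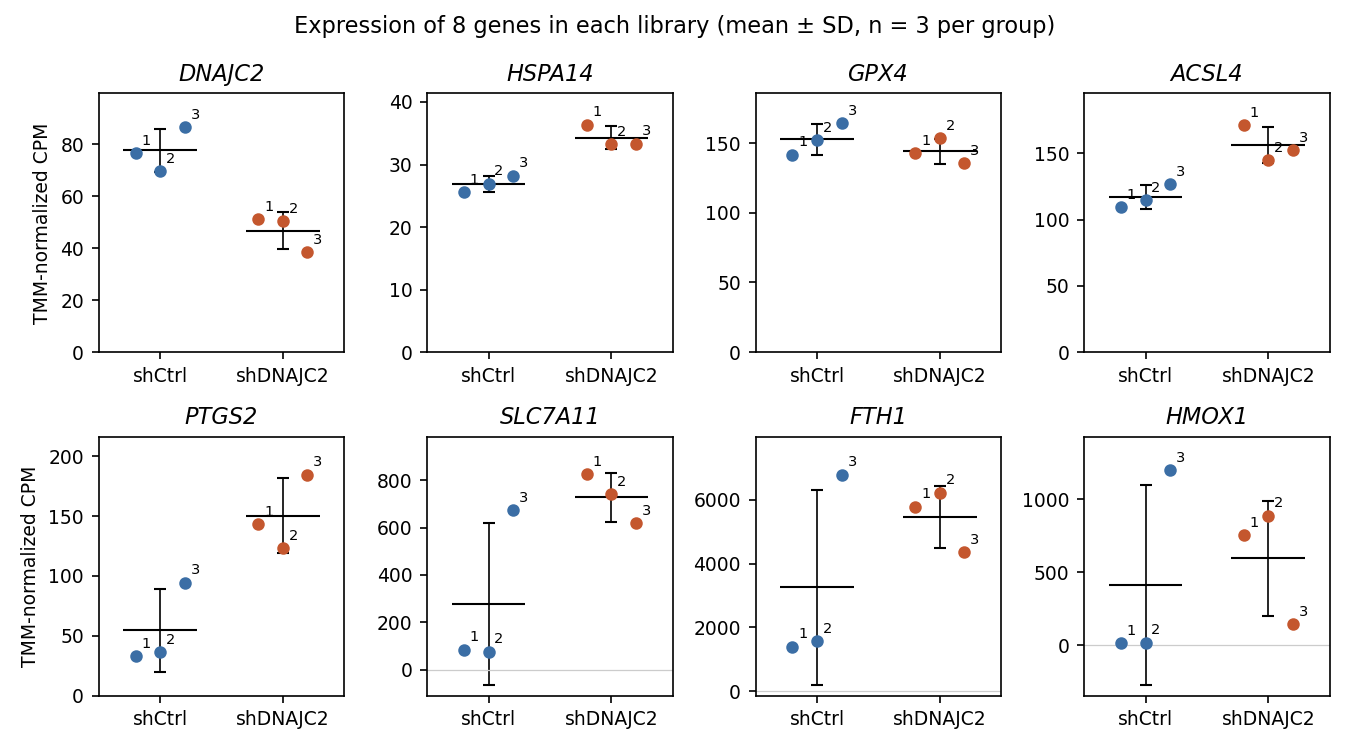
TMM-normalized CPM of 8 genes in each library, with replicate numbers beside the points, horizontal lines for group means and bars for ± SD (n = 3 per group). DNAJC2, HSPA14, ACSL4 and PTGS2 do not overlap between groups, GPX4 does, and for SLC7A11, FTH1 and HMOX1 the control numbered 3 lies at 673, 6790 and 1198 CPM, among or above the knockdown libraries. The panel genes AIFM2, TFRC, NCOA4, LPCAT3 and NFE2L2 are not shown, and each overlaps between groups. PTGS2 is not a panel gene and was named for its small p. The groups did not overlap for 15.8% of all genes tested.

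Of the 35 gene lists fixed in advance, 34 had enough expressed members. By camera with a preset correlation between genes, 12 were shifted higher and 6 lower in the knockdown. Some lists shared members, so these 18 are not separate results. SLC7A11, for example, was in the ATF4, NRF2 and ferroptosis-restraining lists, and ALDH1L2 in the ATF4 and serine lists. With an estimated correlation camera called 0 (smallest adjusted p = 0.517, 1 list at an unadjusted p under 0.05), and the rotation test fry called 0 (smallest adjusted p 0.232, 3 lists at an unadjusted p under 0.05). Each list call given here therefore rested on the preset correlation. With the mean of the ATF4 list in each library as a covariate, a setting added after the data had been seen, 15 of the 18 calls ended, those of NF-kappaB targets and mesenchymal genes stayed, and that of interferon-stimulated genes turned. The ATF4 list was among the 15, and the model itself removed its shift. Of the other 14, camera's direction turned for glycolysis (median −0.14), mitotic (0.03), ribosome assembly (−0.08) and ribosomal protein genes (0.01, with a lower direction). Hypoxia genes kept a higher direction at a median of −0.02. Medians were 0.10 for NRF2 targets and −0.05 for cholesterol synthesis, and genes that favour ferroptosis kept their median of 0.07. None of the 3 remaining calls passed with an estimated correlation (adjusted p = 0.773, 0.773 and 0.805). In edgeR over all 6 libraries no list member passed when adjusted over all genes. Adjusted over the list alone, DNAJC2 among the ribosome-associated chaperones, CORO1A among blood and immune genes and CSPG4 among fibroblast genes passed, all lower.

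Targets of ATF4, the transcription factor of the integrated stress response, had the largest median rise of the lists, 0.86 over 35 members, all 35 with a positive log2 fold change (camera adjusted p 2.3e-11, adjusted p = 0.517 with an estimated correlation). Their mean level relative to the 6-library mean was −1.81 and −1.74 in shCtrl 1 and 2, 1.16 in shCtrl 3, and 0.99, 1.06 and 0.33 in shDNAJC2 1, 2 and 3 on the log2 scale. Without shCtrl 3 all 35 rose, with a median of 2.75, against 0.42 without shCtrl 1. ALDH1L2, a mitochondrial folate enzyme, was at 14.8, 14.3 and 98.9 CPM in the controls and 118, 105 and 99.4 CPM in the knockdown libraries. The glycine transporter gene SLC6A9 rose by 2.91 without shCtrl 3. Among the 8 largest rises without that library were the asparagine synthetase gene ASNS (4.21), the amino acid transporter gene SLC7A5 (4.11), the mTORC1 inhibitor gene DDIT4 (5.01) and INHBE (4.57), together with HMOX1, FOSB (5.90), IL24 (4.38) and ADM2 (4.10). ASNS was at 29.1, 30.6 and 581 CPM in shCtrl 1, 2 and 3 and at 645, 608 and 396 CPM in shDNAJC2 1, 2 and 3.

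NRF2 targets and glutathione genes shifted higher, with a median of 0.51 over 32 members, 31 of them positive (camera adjusted p 3.3e-09, adjusted p = 0.517 with an estimated correlation). Without shCtrl 3 (median 0.93, against 0.28 without shCtrl 1), 28 of the 32 rose and 0 fell, among them SLC7A11 and the sulfiredoxin gene SRXN1 (1.89). Genes that restrain ferroptosis shifted higher (median 0.29 over 28, camera adjusted p 0.0057), as did genes that favour it (median 0.07 over 30, adjusted p 0.0084) and iron-handling genes (median 0.12 over 29, adjusted p 0.0084). Each had an adjusted p = 0.517 with an estimated correlation. Without shCtrl 3, 14 of the restraining genes rose and 4 fell (median 0.48), and 11 of the favouring genes rose and 1 fell (median 0.13). Within the restraining list GCLM, a subunit of the enzyme that starts glutathione synthesis, rose by 2.23, while the small heat shock protein gene HSPB1 fell by 1.39. HSPB1 was at 277, 287 and 138 CPM in the controls and 98.3, 111 and 112 CPM in the knockdown libraries, without overlap. Of the 29 iron genes 12 rose and 2 fell without shCtrl 3 (median 0.29), including the iron and zinc importer gene SLC39A14 (1.09).

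Of the metabolic lists, glycolysis (median 0.26 over 25, camera adjusted p 8.9e-04) and serine and one-carbon metabolism (median 0.35 over 23, adjusted p 0.0056) shifted higher. Cholesterol synthesis shifted lower, with all 25 members negative (median −0.24, adjusted p 1.3e-05). With an estimated correlation their adjusted p = 0.621 for glycolysis and 0.517 for the other two. Without shCtrl 3, 16 of the 25 glycolysis genes rose (median 0.53, against 0.10 without shCtrl 1), among them the enolase gene ENO2 (0.68) and PDK1 (1.69), which inhibits pyruvate dehydrogenase. Likewise 16 of the 25 cholesterol genes fell (median −0.42), including the sterol reductase gene TM7SF2 (−1.17), at 6.81, 8.82 and 4.27 CPM in the controls and 3.24, 3.17 and 3.94 CPM in the knockdown. The serine synthesis gene PSAT1 rose by 4.05. FASN, the fatty acid synthase gene, lay at 237, 239 and 263 CPM in the controls and at 154, 188 and 191 CPM in the knockdown libraries, so that here shCtrl 3 stood with the other controls. Its log2 fold change was −0.47 with a standard error of 0.12, unadjusted p 0.0070. The GC content of FASN was 65.3%, against a median of 48.5% for all genes tested, and whether a GC bias contributed was left open. The same limit holds for other named genes without overlap between the groups. GC content was 36.9% for PTGS2, 37.4% for ACSL4, 37.6% for CXCL5 and 43.1% for HSPA14, all higher in the knockdown. It was 64.3% for HSPB1, 60.3% for COL5A1 and 57.2% for TWIST1, all lower, while DNAJC2, at 43.3% and lower, went the other way. Lists of fatty acid synthesis (camera adjusted p 0.556), fatty acid oxidation (0.0515), the tricarboxylic acid cycle (0.228), nuclear respiratory chain genes (0.859) and mitochondrial-genome genes (0.768) did not pass. Without shCtrl 3, 10 of the 26 oxidation genes fell, such as the acyl-CoA dehydrogenase gene ACADS (−1.47), and that list passed (camera adjusted p 0.0174, adjusted p = 0.242 with an estimated correlation). It also passed without shDNAJC2 1 (camera adjusted p 0.0261, adjusted p = 0.642 with an estimated correlation).

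**Figure D3:**
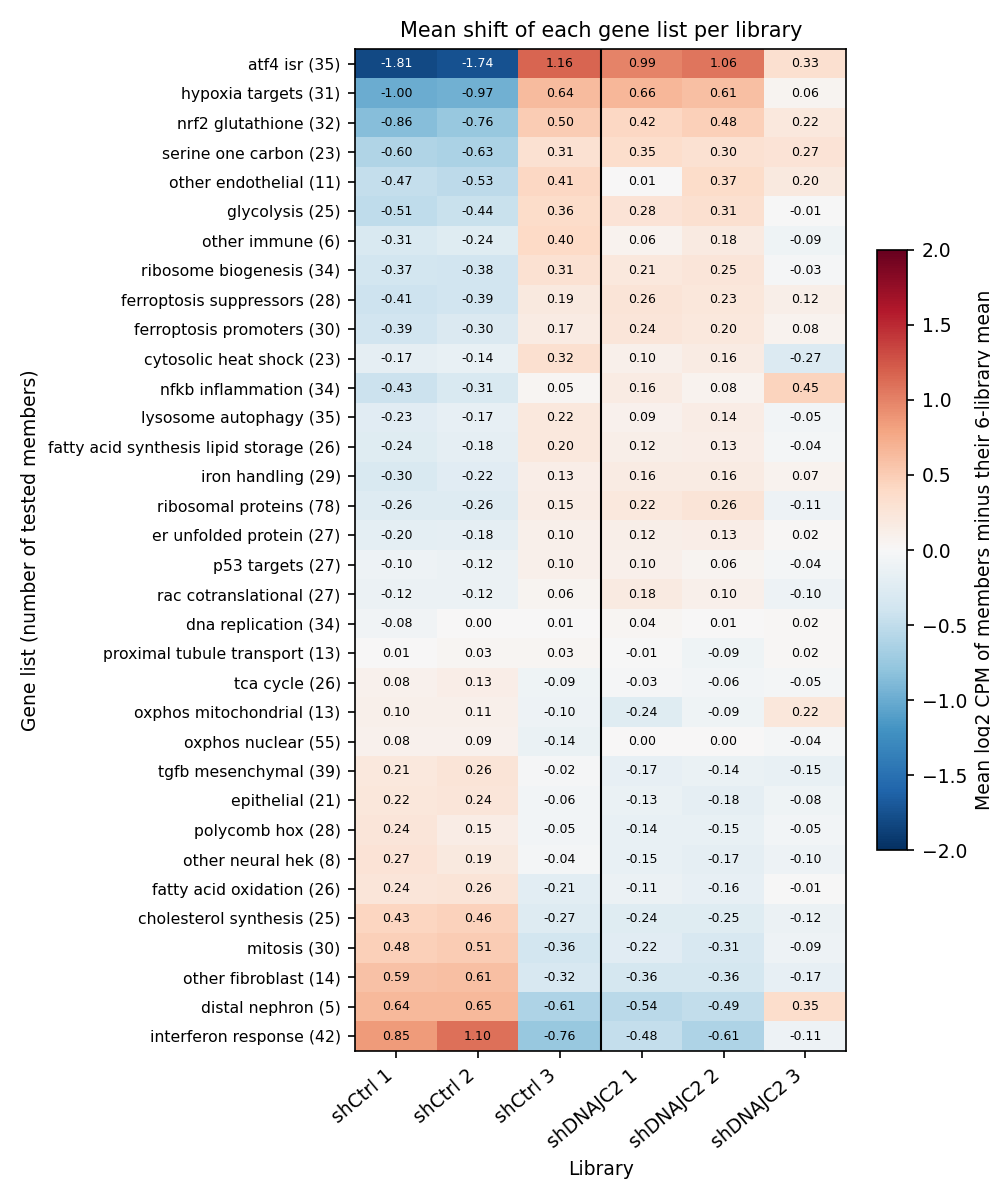
Mean log2 CPM of the members of each gene list minus their mean over the 6 libraries, 1 column per library and 1 row per list, with the number of tested members in brackets and a vertical line between control and knockdown libraries. The ATF4 row runs from −1.81 in shCtrl 1 to 1.16 in shCtrl 3, and the interferon row from 1.10 in shCtrl 2 to −0.76 in shCtrl 3.

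Interferon-stimulated genes shifted lower, with a median of −0.88 over 42 members, 39 of them negative (camera adjusted p 3.5e-11, adjusted p = 0.517 with an estimated correlation). The antiviral gene MX1 was at 400 and 565 CPM in shCtrl 1 and 2, 33.0 CPM in shCtrl 3, and 51.9, 45.8 and 102 CPM in the knockdown libraries. The median was −1.25 without shCtrl 3 and −0.58 without shCtrl 2. Without shCtrl 3, 36 of the 42 fell and 1 rose, and GBP2 (−3.23), IFI44L (−3.01), MX1 (−2.85) and MX2 (−2.77) were among the 8 largest falls, beside HR, the elastin gene ELN, AQP3 and TMT1A. With the ATF4 covariate the interferon list shifted higher, with a median of 0.14 (camera adjusted p 0.0107, adjusted p = 0.805 with an estimated correlation). Mitotic genes shifted lower (median −0.46 over 30, camera adjusted p 3.3e-08, adjusted p = 0.588 with an estimated correlation), and 29 of the 30 fell without shCtrl 3 (median −0.69, against −0.29 without shCtrl 2). The mitotic kinesin gene KIF20A was at 222, 237 and 81.3 CPM in the controls and at 81.0, 79.8 and 94.3 CPM in the knockdown. DNA replication genes did not pass (camera adjusted p 0.229), with 3 that rose and 4 that fell without shCtrl 3.

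HIF targets of hypoxia shifted higher (median 0.56 over 31, camera adjusted p 4.3e-10, adjusted p = 0.517 with an estimated correlation), and 29 of the 31 rose without shCtrl 3 (median 1.46, against 0.37 without shCtrl 1), among them VEGFA (2.11) and the carbonic anhydrase gene CA9 (2.91). Cytosolic ribosomal protein genes (median 0.25 over 78, all positive, camera adjusted p 7.5e-09) and nucleolar ribosome assembly genes (median 0.25 over 34, adjusted p 2.1e-05) also shifted higher, each with an adjusted p = 0.621 with an estimated correlation. Without shCtrl 3, 37 of the 78 (median 0.40) and 26 of the 34 (median 0.52) rose, such as RPL34 (0.57) and the rRNA methyltransferase gene NOP2 (0.63). Without shCtrl 1 the medians of these lists were 0.19 and 0.14. With the ATF4 covariate and the GC trend removed, ribosome assembly genes shifted lower (median −0.09, camera adjusted p 0.0188, adjusted p = 0.976 with an estimated correlation). Ribosomal protein genes share sequence with many pseudogenes. NF-kappaB targets shifted higher (median 0.21 over 34, camera adjusted p 0.0051, adjusted p = 0.517 with an estimated correlation), with 16 that rose and 5 that fell without shCtrl 3 (median 0.42, against 0.06 without shCtrl 1), and this call ended without shDNAJC2 3 (median 0.18, adjusted p 0.164). The cytokine genes IL11 (3.03) and IL1B (2.68) rose without shCtrl 3, and CXCL5, at 67.8, 67.6 and 88.0 CPM in the controls and 120, 101 and 124 CPM in the knockdown, separated the groups.

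Ribosome-associated chaperones, the list that holds DNAJC2 and HSPA14, had a median of 0.14 over 27 members (camera adjusted p 0.019, adjusted p = 0.621 with an estimated correlation). This call ended without shCtrl 3 (median 0.21, adjusted p 0.0739) and without shDNAJC2 1 (median 0.05, adjusted p 0.0959). Without shCtrl 3, 8 members rose and 2 fell, DNAJC2 among the latter, together a share near that of all genes called in that fit (4945 of 14201). The cytosolic heat shock list (camera adjusted p 0.70) and the endoplasmic reticulum unfolded protein list (0.228) did not pass. Without shCtrl 3, the heat shock list had 3 members that rose and 2 that fell, HSPB1 and CRYAB, and the unfolded protein list had 6 that rose and 4 that fell, with HERPUD1 (2.17), the stress sensor gene ERN1 (1.77) and EDEM1 (0.88), a factor of glycoprotein degradation, among those that rose.

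Mesenchymal and matrix genes shifted lower (median −0.29 over 39, camera adjusted p 1.1e-04), as did fibroblast and pericyte markers (median −0.54 over 14, adjusted p 1.8e-04), each with an adjusted p = 0.517 with an estimated correlation. Without shCtrl 3, 15 of the 39 fell and 5 rose, and 8 of the 14 fell and 0 rose. The collagen genes COL5A1 (−1.31) and COL1A1 (−1.88) fell there, and COL1A1 was at 2796, 2785 and 695 CPM in the controls and 572, 623 and 1067 CPM in the knockdown. The identity of the line was not tested, so these lists give levels and not cell types. TWIST1, a transcription factor of mesenchymal cells, was at 30.5, 31.5 and 20.3 CPM against 16.4, 16.6 and 16.4 CPM, without overlap. Epithelial genes shifted lower (median −0.23 over 21, camera adjusted p 0.0233, adjusted p = 0.517 with an estimated correlation), a call that ended without shCtrl 3 (median −0.28, adjusted p 0.215) and without shDNAJC2 3 (median −0.22, adjusted p 0.120), at medians of about the same size. Without shCtrl 3, 7 of the 21 fell and 2 rose, among them the tight junction gene CLDN1 (2.51).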

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

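The residual component, the ATF4 and GC corrections, the use of the fit without shCtrl 3 to name genes and the split counts for genes were chosen after results were seen, the other alternatives before. No cause of a move was tested. With other size factors, other filters, limma-voom or stricter thresholds 0 genes passed, and DNAJC2 kept its direction under every alternative run. DESeq2 called 18 genes (1 of at least 2-fold) and gave DNAJC2 a log2 fold change of −0.72 (adjusted p 0.04997, with a range over all alternatives from 1.1e-04 to 0.886). The residual component as covariate gave 4765 genes (494 of at least 2-fold) and −0.74 for DNAJC2, but other splits of the libraries gave up to 6732 genes, so that count is not specific to the hairpin. Leaving out 1 library gave 0 to 4945 genes, 0 to 1378 of at least 2-fold, −0.81 to −0.60 for DNAJC2 and 17 to 19 lists. The upper values for genes came without shCtrl 3 (DNAJC2 −0.65 there), where the common biological coefficient of variation was 0.118 against 0.227. The number of lists was 6 (3 higher, 3 lower) with the ATF4 covariate, 8 (5 higher, 3 lower) with that and the GC correction, 0 with an estimated correlation and 0 with fry, against 18 by the planned test.

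Same-numbered libraries deviated oppositely (r = −0.382, −0.521 and −0.664), but the first principal axis can set this, so pairing stays open. With a replicate block 0 genes passed, the DNAJC2 log2 fold change was −0.74 and 18 lists passed.

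Under the ATF4 covariate 2 of the 18 called lists kept call and direction, 15 lost the call (4 turned, and the model itself removed the ATF4 shift), and interferon genes passed the other way (median 0.14, adjusted p 0.0107). Nuclear respiratory (0.098), heat shock (−0.14) and lysosome genes (−0.13) newly passed, against their direction over all libraries. With an estimated correlation these 6 did not pass (adjusted p = 0.773 to 0.805). With the GC correction added, 3 kept call and direction beside the ATF4 list, whose shift the model sets, 12 lost the call (3 turned), and interferon (0.13) and ribosome assembly genes (−0.092) passed the other way, but with an estimated correlation adjusted p = 0.976 for both. The next values turned sign but passed neither there nor over all libraries. With the ATF4 covariate they were HMOX1 (−0.66), AIFM2 (−0.15), FTH1 (−0.048) and NCOA4 (0.043). With GC correction too they were HMOX1 (−0.47), AIFM2 (−0.028), FTH1 (−0.031), TFRC (−0.0010), LPCAT3 (0.053) and GPX4 (0.060), and with the GC correction alone GPX4 (0.15). With 1 library left out HMOX1 ranged from −0.024 (without shCtrl 1) to 5.13 (without shCtrl 3, where it passed) and NCOA4 from −0.074 to 0.063. Where the direction of a list's test turned, its median ranged from −0.036 to 0.26 for heat shock, −0.069 to 0.042 for nuclear respiratory genes, −0.14 to 0.011 for mitochondrial-genome genes, −0.10 to 0.054 for proximal tubule genes and 0.050 to 0.62 for blood and immune genes. Medians were 0.16 for the latter with total library size, 0.27 with the replicate block, −0.086 for proximal tubule genes without a filter and 0.070 for p53 targets with fry. Of the other gene and list values, 1257 and 405 kept direction and side of the threshold, 89 and 11 newly passed, and 0 and 41 lost the call. Other size factors moved the median log2 fold change of all genes by less than 0.1.

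All 10 splits of the 6 libraries gave at least the real 0 genes (highest other 4710), all 10 at least the real 0 of 2-fold size (highest other 1143), and 4 gave at least the real 18 lists (highest other 21). Any split reaches 0, so the gene counts test nothing, and 10 splits cannot reach 0.05 for lists. The split with 4710 genes set shCtrl 1, shCtrl 2 and shDNAJC2 3 against the rest, a structure other than the hairpin.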

Other observations

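Of the tests given here, those of a wrong label for shCtrl 3, of the DNAJC2 level and of endoplasmic reticulum stress were chosen after the results they bear on had been seen. Both tests of GC content were set before their own results. The test of GC content under the ATF4 covariate used that covariate and the GC correction, both added after other results had been seen. Genes of kidney identity were scarce in all 6 libraries. Of the 34 proximal tubule genes that were counted, 13 were expressed enough to test, and of 23 genes of the loop of Henle, distal tubule and collecting duct 5 were. PAX8, a kidney lineage transcription factor gene, was at 2.82 to 4.64 CPM, PAX2 had 1 count over all libraries, and the E-cadherin gene CDH1 and the kidney injury marker gene HAVCR1 had 0 counts, below a floor of 0.116 to 0.172 CPM per library. The keratin genes KRT8 and KRT18 were at 30.9 to 41.7 CPM and 66.5 to 89.8 CPM, and the vimentin gene VIM was at 2961 to 4350 CPM. The BMP antagonist gene GREM1 was at 876, 873 and 2432 CPM in the controls and 2906, 2618 and 2648 CPM in the knockdown libraries, and the collagenase gene MMP1 at 981, 987 and 4168 CPM and at 4271, 4639 and 3237 CPM. These genes, apart from list membership, were chosen after their values were seen, and ACHN is the name that the labels give. Low PAX8, nearly absent PAX2, absent CDH1 and high GREM1 and MMP1 leave the identity of the line in doubt, while the epithelial keratins KRT8 and KRT18 were expressed. That identity was not tested, and no reference profile of ACHN was compared. The values of kidney and fibroblast markers therefore do not show what type of cell this is.

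HOX and Polycomb genes did not pass without shCtrl 3 (camera adjusted p 0.0537, against 0.0551 over all libraries), and without shCtrl 2 they passed (0.0414, and adjusted p = 0.577 with an estimated correlation). Without shCtrl 3, 9 of them fell, such as HOXA3 (−1.63) and HOXA5 (−1.60), and 3 rose. Among p53 targets 8 rose and 8 fell without shCtrl 3, led by SESN2 (2.94), a stress sensor gene, and TP53I3 (−1.07), and the list did not pass (adjusted p 0.868 over all libraries). Lysosome and autophagy genes passed only without shCtrl 3 or without shDNAJC2 3 among the fits with 1 library left out (adjusted p 0.0068 and 0.0365, against 0.114 over all, and adjusted p = 0.537 and 0.692 with an estimated correlation), with 14 that rose, among them the autophagy receptor gene SQSTM1 (1.87). Of the marker lists of other cell types, proximal tubule (adjusted p 0.929), distal nephron (0.546), blood and immune (0.929), endothelial (0.215) and neural genes (0.400) did not pass over all libraries, and 3 hepatocyte or intestinal genes were too few to test. Endothelial genes passed without shCtrl 3 (0.0425, and adjusted p = 0.457 with an estimated correlation) and without shDNAJC2 1 (0.0464, and adjusted p = 0.613). The blood and immune list had a positive median (0.18) but a lower direction by camera. The 18 genes that DESeq2 called over all libraries included the transcription factor gene GATA2 (−0.74), the histone gene H2AX (−0.59) and GNGT1 (0.71), named after their values were seen. The median GC content of the 18 was 61.5%, against 48.5% for all genes tested.

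The first pattern was that shCtrl 3 lay apart from shCtrl 1 and shCtrl 2. A knockdown library under a control label was argued against by DNAJC2, which was 0.757 higher on the log2 scale in shCtrl 3 than in the highest knockdown library, against a spread within groups of 0.197. A lower DNAJC2 mRNA level was argued against, since DNAJC2 in shCtrl 3 was above the lower of shCtrl 1 and shCtrl 2 by 0.310 on that scale. GC content and length together explained 1.31% of the variance across genes of the difference between shCtrl 3 and shCtrl 1, but 55.9% of that of the loadings of the second principal component, which had shCtrl 3 (22.3) and shDNAJC2 1 (−21.2) at its ends. A mix-up with a control sample from outside the series, or a difference in culture, harvest or batch that the labels do not record, may account for it and stays open.

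The second pattern was the high level of ATF4 targets in shCtrl 3 and the knockdown libraries. Endoplasmic reticulum stress stays open as a cause, because members of the unfolded protein list that are in no other list went both ways between shCtrl 3 and shCtrl 1 (14 higher, 12 lower, median log2 difference 0.065, SD 0.963), and that median, 2.30% of the 2.81 of the ATF4 list, decides nothing. HERPUD1, at 20.9 and 22.0 CPM in shCtrl 1 and 2, was at 110 CPM in shCtrl 3, and ERN1 was at 9.27 and 8.86 CPM against 40.8 CPM, while HSPA5, the main chaperone of that compartment and chosen after its values were seen, was at 671 and 680 against 815 CPM. Of the 12 lower members, CALR and CRELD2, also chosen after their values were seen, differed by −0.76 and −0.97 (log2, shCtrl 3 minus shCtrl 1). Amino acid shortage or another culture condition might also raise ATF4 targets and was not tested. Whether lower DNAJC2 contributed in the knockdown libraries stays open too, since shCtrl 3 was high at a control level of it. Of the knockdown libraries, shDNAJC2 3 had the lowest DNAJC2, at 38.5 CPM against 51.2 and 50.4 CPM in shDNAJC2 1 and 2. It also had the smallest mean shift of the ATF4 list, 0.33 against 0.99 and 1.06.

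The third pattern appeared when the mean of the ATF4 list entered the model. DNAJC2 then ranked 1 by p, with a log2 fold change of −0.90 (standard error 0.13), but edgeR called 0 genes at an adjusted p of 0.05 (smallest 0.0948, 2414 at an unadjusted p under 0.05), and of 175 genes under 0.1 there were 154 lower. The 154 had a median GC content of 63.4%, and Spearman's rho between log2 fold change and GC content across genes was −0.644. They were selected as lower in these same libraries, so the size kept after a GC correction cannot measure a part free of GC. How much a GC bias may contribute therefore stays open. After the GC trend of each library was removed, the median log2 fold change of the 154 went from −0.52 to −0.27, or 52.7% of its size. After it 1 gene stayed under 0.1, DNAJC2 itself (−1.02, standard error 0.11, adjusted p 0.0599), while 8 lists, 1 of them the ATF4 list itself, passed camera, 0 of them with an estimated correlation (smallest adjusted p = 0.976), among them heat shock (22 of 23 negative), interferon (31 of 42 positive) and ribosome assembly (26 of 34 negative), all against their direction over all libraries. The ATF4 mean was itself measured from these libraries, so this model holds fixed a quantity that the knockdown might change.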
